A study of Homo sapiens with 12 samples.

How the data were processed

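RNA was sequenced from A549 cells, a human lung adenocarcinoma line, 72 h after reverse transfection with siGOLM1-2, siGOLM1-1 or a control siRNA labelled non-targeting, each at 50 nM. Each of the 3 groups had 4 libraries, which are biological replicates per the labels. Per the labels' protocols, the libraries were made from total RNA with a stranded mRNA kit and sequenced in paired-end mode. The authors demultiplexed reads with bcl2fastq 2.20, aligned them with STAR 2.7.3 to hg19 and used DESeq2 1.24.0, per the submitters' processing notes. The read counter, the annotation release and the strand setting were not given in the sources used here. Overlapping and antisense genes, and members of near-identical families, are therefore uncertain; among the genes named below this holds for the CEACAM, mucin, HLA and histone genes and the mitochondrial transcripts.

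The deposited table held raw counts per gene for 57773 genes, and 24653 of them had no count in any library. The deposited tables for each siRNA held the same counts as the full table. The deposited result tables of the authors gave, per the file headers, a mean normalised signal, a log2 fold change with its standard error, a Wald statistic (score), a p-value and an adjusted p-value for 30028 genes. The mean of a gene was the same in both tables. Those tables were used only for a comparison of calls and of the GOLM1 fold changes.

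Total counts ran from 41.6 M to 71.3 M per library. Differences were computed with edgeR 4.0.16 in R 4.3.3. Genes were kept with filterByExpr, which left 17532 genes, and libraries were scaled with TMM factors. All 12 libraries entered one quasi-likelihood fit with robust dispersion and 9 residual degrees of freedom, and its common biological coefficient of variation was 0.146. Each siRNA was compared with the control, and siGOLM1-1 was compared with siGOLM1-2. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, and every adjusted p given for a gene comes from this edgeR test unless another tool is named. Standard errors of genes are on the log2 scale, with n = 4 libraries per group. The fit treats the libraries as independent, although the control libraries deviated in pairs, as described below. Standard errors and adjusted p against control may therefore be too small. CPM values were computed here from the deposited counts, divided by the library total scaled with its TMM factor.

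Before the data were examined, 31 gene lists and the rule for named genes were written down. The lists hold 846 different genes, 20 of them in more than 1 list. Lists were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over the 31 lists within a comparison, and again with an estimated correlation and with fry, which does not compare a list with other genes. The lists cover Golgi structure proteins, vesicle coats and Golgi transport, Golgi glycosyltransferases, the unfolded protein response, the amino acid response, cholesterol synthesis, fatty acid and lipid storage, DNA replication, mitosis, p53 targets, the interferon response and antigen presentation. They also cover NF-kB and cytokines, AP-1 and immediate early genes, epithelial genes, mesenchymal genes, TGF-beta targets, matrix proteases and inhibitors, matrix and basement membrane, YAP and TEAD targets, receptor tyrosine kinases and PI3K, hypoxia and glycolysis, and NRF2 targets. The rest are lysosome and autophagy genes, ribosomal proteins, nuclear respiratory chain genes, mitochondrial transcripts, histone genes, the RNAi machinery, lung lineage genes and markers of other cell types.

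The rule for named genes allowed GOLM1 and a fixed set of genes, of which MMP13 was not among the genes tested. It further allowed, per siRNA, the 6 largest called rises and falls with a mean of at least 5 CPM in the higher group and no overlap between the groups' libraries. It allowed the 8 largest rises and falls shared by both siRNAs under the same conditions, the 5 largest differences in each direction between the siRNAs among genes called in opposite directions, and the 4 members of each list with the smallest p. Of the last part, the 2 members with the smallest p per list and comparison were used. Some genes that the rule allowed are not reported here and were left out of counts over the named genes. The narrowing to 2 members was set after the values and the alternatives had been seen, and it replaced an earlier choice of members made by hand.

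The 3' UTR of 13675 genes, 78.0% of the genes tested, was taken from GENCODE release 29, matched by gene and used without coordinates because the counts were made on another build. That share is under 80%, so a check over all genes tested is void, and the word results hold for the genes with an annotated 3' UTR alone. For 16219 words of 7 bases, log2 fold changes of genes with and without the word were compared by a rank-sum test with Bonferroni adjustment.

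The computations were tested on simulated data with 200 changed genes among 17532. In the simulation of siGOLM1-1 against control, 36.4% of genes changed by 0.5 on the log2 scale were called, 77.6% of those changed by 1 and 85.1% of those changed by 1.5, with 7 false calls. In that of siGOLM1-2 against control the shares were 39.4%, 71.6% and 82.1%, with 6 false calls. A shift of 0.4 planted in the p53 target list ranked 1 among the lists, with 0 other lists called, in both simulations. Genes were drawn independently there, so the simulations do not test the list calls under the correlation between genes in the data. With siGOLM1-1 against control, that correlation was estimated at 0.284 for p53 targets and 0.837 for mitosis. All 3 planted words were found in the test of the word search.

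Alternatives were other scaling methods, other filters on low counts, DESeq2 1.42.0, limma-voom, only the 8 libraries of a comparison, a replicate block, thinned counts, each library left out in turn, a stricter threshold and a test against a minimum change. Alternatives added after the data were seen were each pair of control libraries alone (replicates 1 and 2, or 3 and 4), 1 surrogate variable from sva 3.50.0, and fits without genes or list members that hold a word. No library was left out of the results given in the report.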

Results

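Gene expression was measured by RNA sequencing in A549 lung adenocarcinoma cells transfected with siGOLM1-2, siGOLM1-1 or a control siRNA labelled non-targeting, with 4 biological replicates per group per the labels. The comparisons ask which transcripts differ when GOLM1, which encodes a Golgi membrane protein, is silenced, and how far the 2 siRNAs differ from each other. Total counts averaged 47.4 M in the control, 57.3 M with siGOLM1-1 and 50.1 M with siGOLM1-2, and ran from 41.6 M to 71.3 M over the libraries. Mitochondrial transcripts took 6.28% ± 1.31 (SD, n = 4) of the counts in the control, 4.10% ± 0.70 with siGOLM1-1 and 6.01% ± 1.14 with siGOLM1-2.

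GOLM1 (ENSG00000135052) was lower in each of the 8 knockdown libraries than in each control library. The control libraries held 344.5 to 378.1 CPM, the siGOLM1-1 libraries 37.48 to 38.94 CPM and the siGOLM1-2 libraries 44.57 to 53.43 CPM. GOLM1 was 9.52-fold lower with siGOLM1-1 (log2 fold change -3.25, SE 0.07, adjusted p = 4.97e-12) and 7.72-fold lower with siGOLM1-2 (-2.95, SE 0.07, adjusted p = 1.57e-11). This left 10.5% and 13.0% of the control level. The authors' deposited tables, made with DESeq2, gave -3.24 and -2.93.

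**Figure D1:**
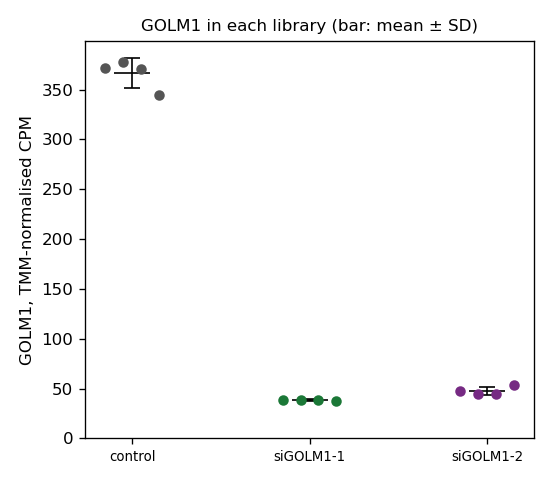
GOLM1 in TMM-normalised CPM for each library by group, with the mean and SD of 4 replicates. All knockdown libraries lie at 53.43 CPM or below and all control libraries at 344.5 CPM or above.

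The control libraries fell into 2 pairs. After group means were removed, control replicates 1 and 2 deviated together (correlation 0.70 across genes, which are not independent replicates), as did replicates 3 and 4 (0.83). Correlations between the pairs ran from -0.90 to -0.85. Deviations from a group mean cancel out within the group for each gene, so these are negative in part by construction. Deviations were also shared across groups: those of siGOLM1-1 replicate 1 correlated at 0.50 with control replicate 1, at 0.60 with siGOLM1-2 replicate 2 and at -0.64 with siGOLM1-2 replicate 4. The main fit does not model these shared deviations, so standard errors, adjusted p and counts of calls against control may be too favourable. Principal components 1, 2 and 3 of the log2 CPM values held 44.6%, 27.7% and 9.66% of the variance.

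**Figure D2:**
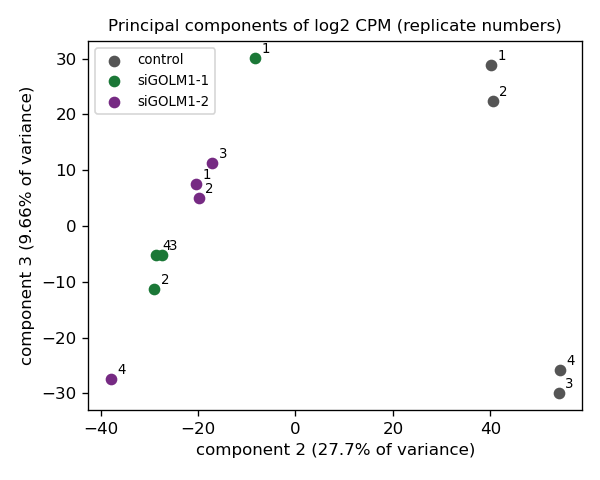
Principal components 2 and 3 of log2 CPM for the 12 libraries, with replicate numbers. Control replicates 1 and 2 lie apart from replicates 3 and 4 on component 3, which holds 9.66% of the variance, as do siGOLM1-1 replicate 1 and siGOLM1-2 replicate 4 from the rest of their groups.

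Rankings of rises and falls hold for genes with a mean of at least 5 CPM in the higher group and no overlap between the groups' libraries. With siGOLM1-1, the largest rises in that set were in RASD1, a small GTPase (log2 fold change 4.97, SE 0.40), TMEM173, the adaptor STING of DNA sensing (4.62, SE 0.41), and SPNS2, a sphingosine-1-phosphate transporter (4.55, SE 0.55). C10orf10 (4.08), CEACAM7 of the CEACAM adhesion family (3.97) and H19, an imprinted non-coding RNA (3.55), followed. The largest falls in that set were in METTL7A (-4.94, SE 0.71), C1orf116 (-3.93), PRR15L (-3.48), GOLM1, MEST, an imprinted gene (-3.22, SE 0.09), and C12orf39, which encodes the peptide spexin (-3.03). All 12 changes had edgeR adjusted p of 0.0011 or less. Several of these folds depended on the control pair. With control replicates 1 and 2 alone, METTL7A was at -3.28, C1orf116 at -2.91, PRR15L at -1.21, C12orf39 at -2.35, CEACAM7 at 4.86, RASD1 at 4.26, SPNS2 at 3.86 and H19 at 3.11. With replicates 3 and 4 alone, they were at -5.67, -4.51, -4.31, -3.47, 3.45, 6.36, 5.84 and 4.18 in that order. METTL7A was at -5.78 without siGOLM1-1 replicate 1.

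Of the 17532 genes tested with siGOLM1-1, 8333 (47.5%) were called, 4152 higher and 4181 lower. With library totals alone as the scaling, the calls were 3606 higher and 4772 lower, a share of 43.0% higher against 49.8%. By at least 1 on the log2 scale, 1002 were higher and 1068 lower. The libraries of the groups did not overlap for 7188 genes (41%), where chance gives 2.9%. The authors' deposited table called 8580 genes, and 8096 genes were called in the same direction in both. By camera, 13 of the 31 lists were called, 10 up and 3 down, and 0 were called with an estimated correlation (lowest adjusted p = 0.295; 3 lists at an unadjusted p under 0.05).

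Genes of DNA replication fell with siGOLM1-1: of 39 members, 0 were higher, 36 lower and 3 not called (36 lower adjusted over the list alone), with median -0.75 and camera adjusted p = 3.41e-18 (adjusted p = 0.297 with an estimated correlation). MCM3, a subunit of the replicative helicase, was at -1.44 (SE 0.09), and CHAF1B, a chromatin assembly factor, at -1.31 (SE 0.09). Mitosis genes fell as well, with 1 higher, 22 lower and 17 not called of 40 (1 and 23 adjusted over the list alone) and median -0.45, camera adjusted p = 0.000138 (adjusted p = 0.742 with an estimated correlation). The mitosis median was -0.63 against control replicates 1 and 2 alone and -0.25 against replicates 3 and 4 alone (camera adjusted p = 0.019), and the DNA replication median -0.90 and -0.62. The mitotic kinase AURKA was at -2.56 (SE 0.14) and its activator TPX2 at -1.86. Histone genes rose, with 7 higher, 2 lower and 3 not called of 12 (9 and 2 adjusted over the list alone; median 0.69, camera adjusted p = 0.00015, adjusted p = 0.297 with an estimated correlation). HIST2H2BE was at 1.58 and the linker histone HIST1H1C at 1.85. Of the 18 histone genes listed, 12 passed the filter, and the values hold for transcripts in mRNA libraries alone. Mitochondrial transcripts fell, with 0 higher, 9 lower and 4 not called of 13 (0 and 10 adjusted over the list alone; median -0.60, camera adjusted p = 0.0337, adjusted p = 0.742 with an estimated correlation), and MT-CO2 was at -0.67 and MT-ATP6 at -0.68. That call ended in 6 of 22 alternatives: without control replicate 2 (median -0.47), siGOLM1-1 replicate 1 (-0.56) or siGOLM1-1 replicate 2 (-0.51), with control replicates 3 and 4 alone (-0.51), with 1 surrogate variable (-0.59) and with a filter of at least 1 CPM in at least 4 libraries (-0.61). Its camera adjusted p ran from 0.00052 to 0.0791.

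Some stress-response lists rose with siGOLM1-1, while those of the unfolded protein response (camera adjusted p = 0.184) and of hypoxia and glycolysis (0.376) were not called. NRF2 targets, which serve oxidative defence, had 23 members higher, 3 lower and 6 not called of 32 (23 and 3 adjusted over the list alone), with median 0.73, camera adjusted p = 4e-10 (adjusted p = 0.295 with an estimated correlation). Heme oxygenase HMOX1 was at 2.06 (SE 0.13) and thioredoxin reductase TXNRD1 at 1.40 (SE 0.09). Of the p53 targets, 18 were higher, 3 lower and 7 not called of 28 (20 and 5 adjusted over the list alone; median 0.42, camera adjusted p = 1.87e-06, adjusted p = 0.297 with an estimated correlation). The pro-apoptotic BBC3 was at 1.78 and the antiproliferative BTG2 at 2.11. Genes of the amino acid response had 18 higher, 4 lower and 7 not called of 29 (18 and 4 adjusted over the list alone; median 0.33, camera adjusted p = 0.000277, adjusted p = 0.312 with an estimated correlation), with SESN2 at 1.25 and VLDLR at 1.16. AP-1 and immediate early genes had 13 higher, 2 lower and 13 not called of 28 (14 and 2 adjusted over the list alone; median 0.47, camera adjusted p = 0.000277, adjusted p = 0.312 with an estimated correlation), with the phosphatase DUSP5 at 3.20 and JUND at 1.72. Lysosome and autophagy genes had 19 higher, 2 lower and 11 not called of 32 (19 and 3 adjusted over the list alone; median 0.42, camera adjusted p = 0.000216, adjusted p = 0.467 with an estimated correlation). The member with the smallest p, the autophagy gene BECN1, was lower (-0.94), and the saposin precursor PSAP was at 0.82.

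Lists of Golgi enzymes, proteases and mesenchymal genes rose with siGOLM1-1. Golgi glycosyltransferases had 17 higher, 4 lower and 6 not called of 27 (18 and 4 adjusted over the list alone; median 0.27, camera adjusted p = 0.00736, adjusted p = 0.297 with an estimated correlation), with GALNT1 at 1.10 and MAN2A2 at -1.05. That call ended without the members that lack an annotated 3' UTR or hold a 7-base word, although the median rose to 0.44 over fewer members (camera adjusted p from 8.27e-05 to 0.0599 over 23 alternatives). The words meant here and below are 1 for each siRNA, whose genes were lower with it more often than other genes. A further word was chosen after adjustment for 3' UTR properties, and its genes were higher with both more often than other genes. Matrix proteases and inhibitors had 15 higher, 2 lower and 10 not called of 27 (15 and 2 adjusted over the list alone; median 0.56, camera adjusted p = 0.000385, adjusted p = 0.295 with an estimated correlation), with the sheddase ADAM17 at 1.09 and TIMP2 at 1.28. TGF-beta targets had 11 higher, 3 lower and 12 not called of 26 (11 and 3 adjusted over the list alone; median 0.26, camera adjusted p = 0.0209, adjusted p = 0.297 with an estimated correlation), with TGIF1 at 0.92 and BAMBI at 0.83. Mesenchymal genes had 14 higher, 4 lower and 14 not called of 32 (15 and 4 adjusted over the list alone; median 0.32, camera adjusted p = 0.028, adjusted p = 0.297 with an estimated correlation), with SERPINE2 at 2.18 and TGFBI at 0.88. The mesenchymal call ended with a filter of at least 1 CPM in at least 4 libraries (median 0.19, camera adjusted p = 0.0703).

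The other 18 lists were not called with siGOLM1-1. Their camera adjusted p was 0.0692 for Golgi structure proteins, 0.778 for vesicle coats and Golgi transport, 0.184 for the unfolded protein response, 0.0653 for cholesterol synthesis, 0.416 for fatty acid and lipid storage and 0.243 for the interferon response. It was 0.376 for antigen presentation, 0.0653 for NF-kB and cytokines, 0.287 for epithelial genes, 0.791 for matrix and basement membrane, 0.184 for YAP and TEAD targets, 0.376 for receptor tyrosine kinases and PI3K and 0.376 for hypoxia and glycolysis. It was 0.416 for ribosomal proteins, 0.156 for nuclear respiratory chain genes, 0.426 for the RNAi machinery, 0.416 for lung lineage genes and 0.981 for markers of other cell types. Of 23 alternatives, 8 called cholesterol synthesis lower, 5 NF-kB and cytokines higher and 3 nuclear respiratory chain genes lower. Golgi structure proteins and the unfolded protein response were called higher in 2 each, and ribosomal proteins in 1. Median, mean and test differed in sign for vesicle coats and Golgi transport (median 0.08, mean -0.02, test down), matrix and basement membrane (median 0.04, mean -0.01, test up) and markers of other cell types (median -0.24, test up). Among the members of these lists, the receptor MET was at -1.46, the matrix protein TNC at -2.27 and the sterol enzyme DHCR7 at -0.76.

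With siGOLM1-2, the largest rises among genes with at least 5 CPM in the higher group and no overlap between the groups' libraries were in DMBT1, a mucosal scavenger receptor (6.38, SE 0.37), the trefoil peptide TFF1 (5.15, SE 0.41), the cytokine IL6 (5.08, SE 0.69), the mucin MUC2 (4.81), the chemokine CCL5 (4.79) and C4BPB, a complement regulator (4.74). The largest falls in that set were in SCNN1A, a sodium channel subunit (-3.49, SE 0.80), FKBP5, a co-chaperone of the glucocorticoid receptor (-3.32, SE 0.67), the clock gene PER1 (-2.99, SE 0.66), GOLM1, COL20A1 (-2.92, SE 0.42) and MAP2, a microtubule-associated protein (-2.81, SE 0.47). All 12 had edgeR adjusted p of 0.0035 or less. Many of these changes depended on the control pair: control replicates 1 and 2 averaged 13.0 CPM of SCNN1A, 22.7 of FKBP5 and 11.1 of PER1, and replicates 3 and 4 averaged 209, 223 and 108 CPM. With replicates 1 and 2 alone, SCNN1A was at -0.39 and not called, FKBP5 at -0.88, PER1 at -0.56, MAP2 at -1.39, COL20A1 at -3.47, DMBT1 at 5.82, TFF1 at 4.36, CCL5 at 4.04 and MUC2 at 4.30. With replicates 3 and 4 alone, they were at -4.38, -4.16, -3.83, -3.49, -2.04, 7.27, 6.92, 6.32 and 5.59 in that order. Without siGOLM1-2 replicate 4, IL6 was at 4.02, and without control replicate 1, CCL5 was at 5.73. The other siGOLM1-2 libraries held 2.43 to 3.71 CPM of IL6, under the 5 CPM of the ranked set, so its place there rests on that replicate 4.

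**Figure D3:**
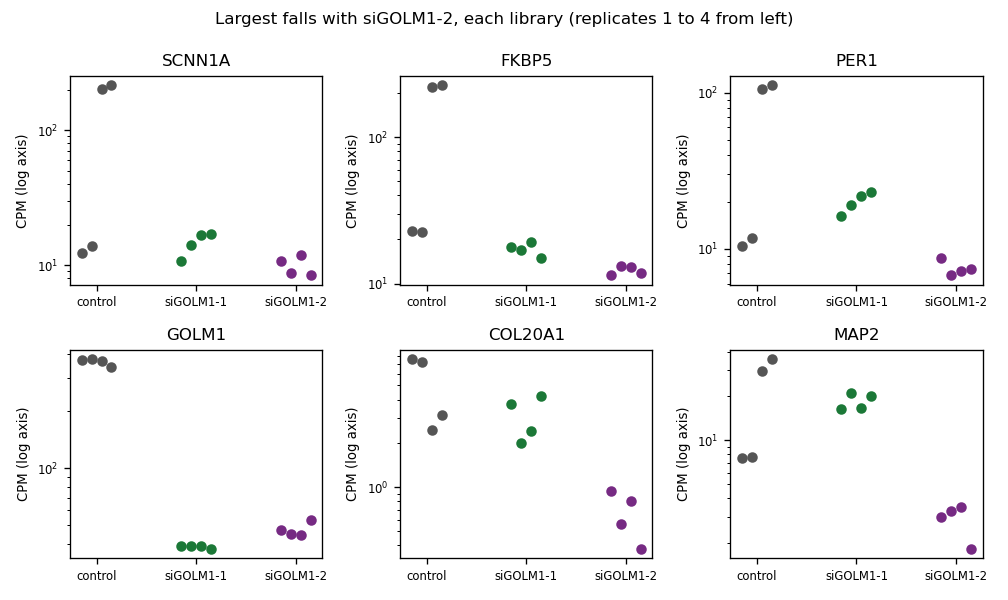
CPM (log axis) of the 6 largest falls with siGOLM1-2, for each library with replicates 1 to 4 from left in each group. Control replicates 1 and 2 held 12.2 and 13.8 CPM of SCNN1A, and replicates 3 and 4 held 203 and 215 CPM.

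Of the 17532 genes tested with siGOLM1-2, 7885 (45.0%) were called, 3814 higher and 4071 lower. With library totals alone as the scaling, the calls were 4682 higher and 3233 lower, a share of 59.2% higher against 48.4%. By at least 1 on the log2 scale, 1141 were higher and 722 lower. The groups did not overlap for 8046 genes (45.9%), where chance gives 2.9%. The authors' deposited table called 8111 genes, and 7586 were called in the same direction in both. By camera, 16 lists were called, 11 up and 5 down, and 0 were called with an estimated correlation (lowest adjusted p = 0.264; 2 lists at an unadjusted p under 0.05).

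Interferon response genes rose with siGOLM1-2, with 30 higher, 2 lower and 8 not called of 40 (31 and 2 adjusted over the list alone), median 0.95 and camera adjusted p = 1.87e-12 (adjusted p = 0.264 with an estimated correlation). The secreted glycoprotein LGALS3BP was at 1.01 (SE 0.08) and the antiviral gene OASL at 3.48 (SE 0.32). Antigen presentation genes had 18 higher, 3 lower and 4 not called of 25 (19 and 5 adjusted over the list alone; median 0.58, camera adjusted p = 2.3e-05, adjusted p = 0.343 with an estimated correlation), with the peptide transporter TAP1 at 0.89 and HLA-E at 0.76. NF-kB and cytokine genes had 17 higher, 2 lower and 11 not called of 30 (17 and 2 adjusted over the list alone; median 0.94, camera adjusted p = 6.41e-05, adjusted p = 0.3 with an estimated correlation), with CCL5 at 4.79 and the NF-kB subunit NFKB1 at 0.66. Matrix proteases and inhibitors had 16 higher, 2 lower and 9 not called of 27 (16 and 3 adjusted over the list alone; median 0.59, camera adjusted p = 0.000501, adjusted p = 0.264 with an estimated correlation), with MMP7 at 1.36 and TIMP1 at 1.11. Matrix and basement membrane genes had 15 higher, 5 lower and 11 not called of 31 (15 and 6 adjusted over the list alone; median 0.36, camera adjusted p = 0.00146, adjusted p = 0.3 with an estimated correlation), with TNC at 2.31 and nidogen NID1 at 1.49.

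Proliferation and lipid lists fell with siGOLM1-2. Mitosis genes had 1 higher, 35 lower and 4 not called of 40 (1 and 36 adjusted over the list alone), median -0.92 and camera adjusted p = 2.69e-13 (adjusted p = 0.343 with an estimated correlation). The checkpoint gene MAD2L1 was at -2.56 (SE 0.18) and the kinase AURKB at -0.92. DNA replication genes had 1 higher, 34 lower and 4 not called of 39 (1 and 34 adjusted over the list alone; median -0.67, camera adjusted p = 4.87e-13, adjusted p = 0.3 with an estimated correlation), with CHAF1B at -1.12 and the clamp loader gene RFC4 at -0.90. Cholesterol synthesis had 1 higher, 13 lower and 10 not called of 24 (1 and 16 adjusted over the list alone; median -0.31, camera adjusted p = 3.55e-05, adjusted p = 0.3 with an estimated correlation), with DHCR7 at -1.09. Fatty acid and lipid storage genes had 4 higher, 13 lower and 11 not called of 28 (4 and 13 adjusted over the list alone; median -0.06, camera adjusted p = 0.00594, adjusted p = 0.3 with an estimated correlation), with the desaturases SCD at -1.08 and FADS2 at -0.87. Hypoxia and glycolysis genes had 3 higher, 18 lower and 14 not called of 35 (4 and 18 adjusted over the list alone; median -0.31, camera adjusted p = 0.00246, adjusted p = 0.523 with an estimated correlation), with PFKFB3 at -1.07 and PGAM1 at -0.70. The fatty acid list was not called with control replicates 1 and 2 alone (median -0.01) or without members that hold a word or lack an annotated 3' UTR (median 0.02), with camera adjusted p from 0.000267 to 0.113 over 23 alternatives. The hypoxia list was not called with control replicates 1 and 2 alone (median -0.23), with camera adjusted p from 1.03e-05 to 0.0633.

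Further lists rose with siGOLM1-2. Of the p53 targets, 18 were higher, 1 lower and 9 not called of 28 (20 and 1 adjusted over the list alone; median 0.63, camera adjusted p = 4.16e-07, adjusted p = 0.3 with an estimated correlation), with SESN2 at 1.11 and CCNG1 lower at -1.63. Lysosome and autophagy genes had 20 higher, 0 lower and 12 not called of 32 (20 and 0 adjusted over the list alone; median 0.25, camera adjusted p = 2.24e-05, adjusted p = 0.331 with an estimated correlation), with the proton pump gene ATP6V1A at 0.83 and the protease CTSB at 1.36. Of the 18 histone genes listed, 12 passed the filter. They had 8 higher, 1 lower and 3 not called (9 and 1 adjusted over the list alone, median 0.73, camera adjusted p = 4.31e-05, adjusted p = 0.3 with an estimated correlation). HIST1H2BK was at 0.95 and HIST1H2AC at 1.28. AP-1 and immediate early genes had 16 higher, 2 lower and 10 not called of 28 (17 and 2 adjusted over the list alone; median 0.38, camera adjusted p = 0.00469, adjusted p = 0.381 with an estimated correlation), with KLF2 at 1.57 and DUSP6 at 1.09. This list was not called with control replicates 1 and 2 alone (median 0.28; camera adjusted p from 3.45e-05 to 0.0633 over 23 alternatives). Epithelial genes had 11 higher, 5 lower and 13 not called of 29 (11 and 5 adjusted over the list alone; median 0.13, camera adjusted p = 0.0122, adjusted p = 0.3 with an estimated correlation), with CEACAM1 at 1.97 and CLDN4 at 2.07. The epithelial list was not called with control replicates 3 and 4 alone (median 0.21), and its median was -0.12 without members that hold a word or lack an annotated 3' UTR (camera adjusted p from 0.00405 to 0.268 over 23 alternatives). Markers of other cell types had 7 higher, 1 lower and 4 not called of 12 (8 and 1 adjusted over the list alone; median 0.68, camera adjusted p = 0.0364, adjusted p = 0.3 with an estimated correlation). PDGFRA of this list averaged 0.524 CPM in the control and 1.90 CPM with siGOLM1-2, and CD14 averaged 7.05 and 11.8 CPM. The call of this list ended without control replicate 3 (median 0.72), without siGOLM1-2 replicate 1 (0.64), with control replicates 1 and 2 alone (0.58), with library totals alone (0.76) and with counts thinned to the smallest library (0.63), and its camera adjusted p ran from 0.00404 to 0.189 over 23 alternatives.

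The other 15 lists were not called with siGOLM1-2. Camera adjusted p was 0.381 for Golgi structure proteins, 0.218 for vesicle coats and Golgi transport, 0.356 for Golgi glycosyltransferases, 0.984 for the unfolded protein response and 0.394 for the amino acid response. It was 0.984 for mesenchymal genes, 0.375 for TGF-beta targets, 0.37 for YAP and TEAD targets, 0.232 for receptor tyrosine kinases and PI3K and 0.769 for NRF2 targets. It was 0.668 for ribosomal proteins, 0.444 for nuclear respiratory chain genes, 0.769 for mitochondrial transcripts, 0.984 for the RNAi machinery and 0.984 for lung lineage genes. Of 23 alternatives, 1 each called TGF-beta targets (control replicates 1 and 2 alone), YAP and TEAD targets (without members that hold a word or lack an annotated 3' UTR) and vesicle coats and Golgi transport (no filter on low counts), all lower. Median, mean and test differed in sign for NRF2 targets (median 0.03, test down), the RNAi machinery (median -0.01, mean 0.03, test down) and lung lineage genes (median -0.18, mean 0.11, test down). In the Golgi structure list, TGOLN2 of the trans-Golgi network was at -1.82 and the cargo receptor TMED10 at -0.94. HMOX1 of the NRF2 list was at -2.26.

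**Figure D4:**
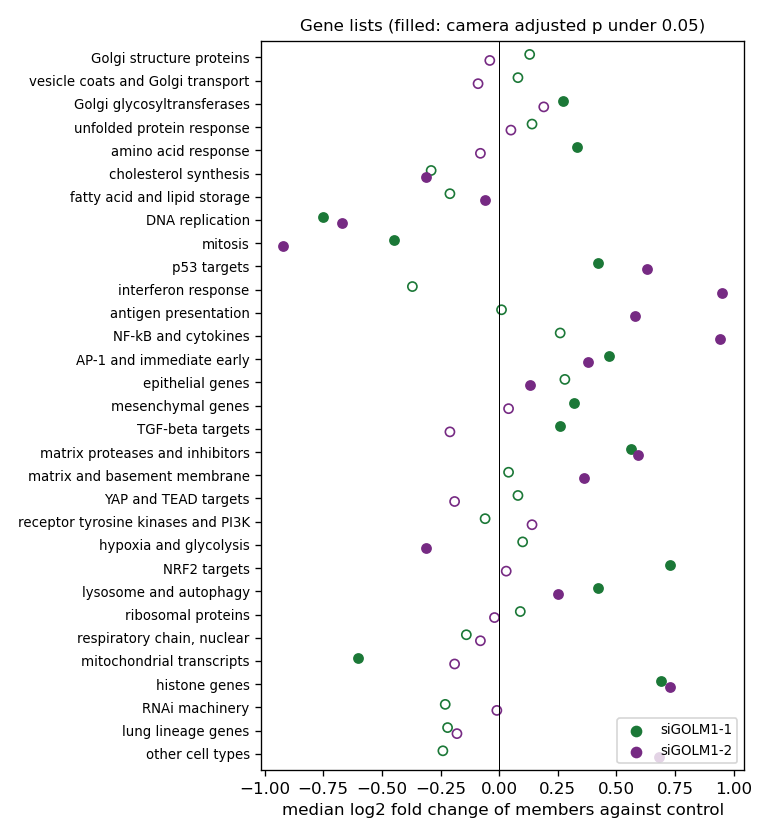
Median log2 fold change of the members of each of the 31 lists with each siRNA against control, filled where camera adjusted p was under 0.05. DNA replication lay at -0.75 and -0.67, mitosis at -0.45 and -0.92.

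Both siRNAs moved some genes alike. Among genes with a mean of at least 5 CPM in the higher group and no overlap with the control libraries for each siRNA, the largest shared rises were in CRISPLD2 (3.53 and 2.67 with siGOLM1-1 and siGOLM1-2), TMOD1, an actin-capping protein (3.22 and 3.19), OSBP2 (2.81 and 2.73), the adhesion gene CEACAM6 (6.48-fold and 6.4-fold), SEMA7A, a semaphorin (2.67 and 2.66), C12orf36 (2.76 and 2.52), SERPINE2, a protease inhibitor (2.18 and 2.39), and the mucin MUC5AC (2.30 and 2.16). SPNS2 (4.55 and 4.03) and TMEM173 (4.62 and 3.81) rose more with both, but averaged 3.77 and 3.69 CPM with siGOLM1-2. SPNS2 with siGOLM1-2 was at 3.33 with control replicates 1 and 2 alone and 5.32 with replicates 3 and 4 alone. The largest shared falls in that set were in GOLM1, FKBP5 (-2.84 and -3.32), MGAM, a glucosidase (-2.59 and -2.65), PTGER4, a prostaglandin receptor (-2.48 and -2.51), TFCP2L1 (-2.81 and -2.01), INSL4 (-1.53 and -1.49), PHGDH of serine synthesis (-1.47 and -1.45) and carbonic anhydrase CA9 (-1.44 and -1.87). SCNN1A (-2.93 and -3.49), METTL7A (-4.94 and -1.75) and PRR15L (-3.48 and -1.68) also fell with both, but their libraries overlapped the control with 1 siRNA. Against control replicates 1 and 2 alone, SCNN1A was at 0.17 with siGOLM1-1 and -0.39 with siGOLM1-2, METTL7A at -0.08 and PRR15L at 0.58 with siGOLM1-2, and none of these was called. The siGOLM1-2 calls of METTL7A and PRR15L also ended without control replicate 3 (-1.35 and -1.15) or 4 (-1.41 and -1.34). They ended as well without siGOLM1-2 replicate 4 (-1.54 and -1.5) and with 1 surrogate variable (-1.35 and -1.1). That of PRR15L further ended without any 1 of the siGOLM1-1 libraries (-1.69), without siGOLM1-2 replicate 1 (-1.7) or 2 (-1.64) and with library totals alone (-1.58). With control replicates 1 and 2 alone, FKBP5 was at -0.40 and -0.88, PTGER4 at -1.43 and -1.47, TFCP2L1 at -1.53 and -0.73, MUC5AC at 1.72 and 1.58 and C12orf36 at 2.29 and 2.05. With replicates 3 and 4 alone, FKBP5 was at -3.69 and -4.16, PTGER4 at -3.06 and -3.09, TFCP2L1 at -3.47 and -2.66, MUC5AC at 3.28 and 3.14 and C12orf36 at 3.44 and 3.20. Without siGOLM1-2 replicate 4, the siGOLM1-2 values were 2.04 for CRISPLD2 and 1.86 for SEMA7A, and without control replicate 1, MUC5AC was at 2.95 and 2.80. That replicate 4 of siGOLM1-2 held 11.9 CPM of SEMA7A, and the other siGOLM1-2 libraries 2.56 to 3.44 CPM. The place of SEMA7A among genes with at least 5 CPM thus rests on 1 siGOLM1-2 library.

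In all, 4400 genes were called with both siRNAs, 3154 in the same direction (1580 higher, 1574 lower) and 1246 in opposite directions. Independent lists of these sizes would share 1874 genes in the same direction. With the controls split between the siRNAs, 1892 to 2456 genes were shared in the same direction and 618 to 1442 in opposite directions. Independent lists of those sizes would share 970 to 1645 in the same direction. Log2 fold changes of the siRNAs correlated at 0.28 across genes, against 0.51 in a simulation of unchanged groups against the same controls, where chance values alone set the spread. Their covariance was 0.141 against 0.029 simulated, a difference of 0.113. The simulation drew libraries independently, without the control pairs, so it cannot show how much covariance those pairs add. With the controls split between the siRNAs, the correlation ran from 0.10 to 0.25 and the covariance from 0.060 to 0.135. Split along the pairs, the covariance was 0.060 where siGOLM1-1 had replicates 1 and 2, and 0.105 where it had 3 and 4. In the other splits each siRNA had a library of each pair, and the covariance ran from 0.124 to 0.135.

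**Figure D5:**
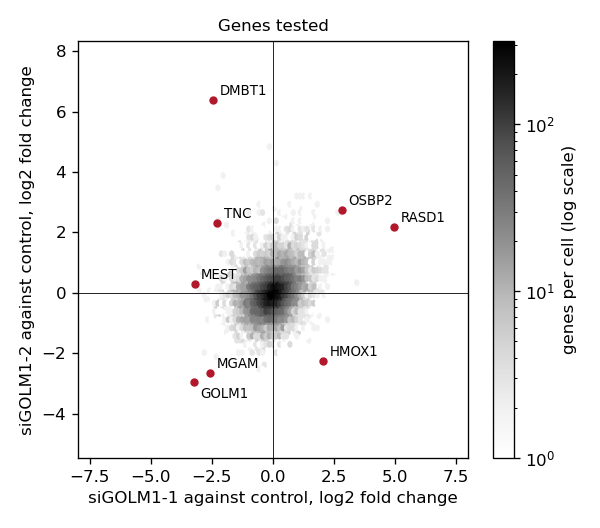
Log2 fold change against control of each gene tested with siGOLM1-1 (horizontal) and siGOLM1-2 (vertical), shaded by the number of genes, with 8 genes marked. GOLM1 lies at -3.25 and -2.95, and HMOX1 at 2.06 and -2.26.

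In the direct comparison of the siRNAs, the controls entered only through the gene filter, the scaling and the dispersion. The genes furthest higher with siGOLM1-1 among those moved in opposite directions were AC079466.1 (log2 difference 5.21, SE 0.57), MAP1LC3C of the autophagy LC3 family (4.96, SE 0.37), HMOX1 (4.32, SE 0.14), DLGAP1 (3.88) and SLC22A31 (3.50). Those furthest lower were DMBT1 (-8.85, SE 0.45), C2CD4A (-7.86, SE 0.45) and C4BPB (-6.80, SE 0.42), with C7 and CD180. The siGOLM1-1 libraries held 0 counts of C7 and CD180, so they were at least 20.6-fold and 129-fold lower than with siGOLM1-2, from 59 and 368 counts over the siGOLM1-2 libraries and a floor of 3 counts over the group. All of these genes but HMOX1 averaged under 1 CPM in the control. Against 1 pair of controls alone, DMBT1 (-1.60), C4BPB (-1.52) and DLGAP1 (1.02) with siGOLM1-1 and C7 (1.32) with siGOLM1-2 were not called. Without siGOLM1-1 replicate 1, C2CD4A was at -9.02, and without siGOLM1-1 replicate 2, DMBT1 was at -9.53. The fall of SLC22A31 with siGOLM1-2 (-0.92, adjusted p = 0.038) was not called without any 1 of control replicates 2, 3 and 4 and siGOLM1-2 replicates 1, 2 and 4, with values from -0.96 to -0.78, nor against either pair of controls alone (-0.76 and -1.05) or with library totals alone (-0.84).

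Between the siRNAs, 9541 genes (54.4%) were called, 4887 higher and 4654 lower with siGOLM1-1. With library totals alone as the scaling, the calls were 3564 higher and 5957 lower, a share of 37.4% higher against 51.2%, and the median of all genes shifted by -0.13. The libraries did not overlap for 8485 genes (48.4%), where chance gives 2.9%. By camera 7 lists were called, 5 up and 2 down, and 0 with an estimated correlation (lowest adjusted p = 0.324; 3 lists at an unadjusted p under 0.05). Interferon response genes were lower with siGOLM1-1 than with siGOLM1-2 (1 higher, 33 lower and 6 not called of 40; median -1.03; camera adjusted p = 1.1e-10, adjusted p = 0.324 with an estimated correlation), with IFI44 at -3.55 and MX1 at -3.59. NRF2 targets were higher (24 higher, 3 lower and 5 not called of 32; median 0.66, camera adjusted p = 3.49e-08, adjusted p = 0.324 with an estimated correlation), as were genes of the amino acid response (15, 2 and 12 of 29; median 0.45, camera adjusted p = 0.000187, adjusted p = 0.502 with an estimated correlation). The folate enzyme MTHFD2 of that list was at 1.69. Hypoxia and glycolysis genes (20, 3 and 12 of 35; median 0.36, camera adjusted p = 0.00324, adjusted p = 0.712 with an estimated correlation) and TGF-beta targets (15, 4 and 7 of 26; median 0.41, camera adjusted p = 0.00925, adjusted p = 0.324 with an estimated correlation) were higher, with KDM3A 2.36-fold higher and TGIF1 at 1.14. Golgi structure proteins were higher (11, 3 and 10 of 24; median 0.12, camera adjusted p = 0.0336, adjusted p = 0.502 with an estimated correlation), with TMED10 at 1.51 and ACBD3 at 1.32. Antigen presentation genes were lower (4, 14 and 7 of 25; median -0.38, camera adjusted p = 0.0336, adjusted p = 0.855 with an estimated correlation), with MICB at -1.45 and TAP1 at -0.96. Adjusted over the list alone, the counts of members higher and lower were the same in these 7 lists. Without siGOLM1-1 replicate 1, the Golgi structure and antigen presentation lists were not called (medians 0.14 and -0.37), nor without members that hold a word or lack an annotated 3' UTR (0.07 and -0.22). The Golgi structure list was also not called with library totals alone (median -0.01) or with a filter of at least 1 CPM in at least 4 libraries (0.10). Camera adjusted p ran from 0.00747 to 0.758 and from 0.00352 to 0.113 over 23 alternatives for these lists.

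The other 24 lists were not called between the siRNAs, with camera adjusted p from 0.0545 for mitosis to 0.899 for lysosome and autophagy. Several of these calls depended on the fit. Mitosis genes were called higher with siGOLM1-1 than with siGOLM1-2 in 14 of 23 alternatives (median 0.46; camera adjusted p from 0.000429 to 0.171; adjusted p = 0.888 with an estimated correlation), among them the replicate block, 1 surrogate variable and either pair of controls. Matrix and basement membrane genes were called lower in 12 (camera adjusted p from 0.0166 to 0.114), YAP and TEAD targets higher in 4 and mesenchymal genes higher in 3. With no filter on low counts, 6 further lists were called. Median, mean and test differed in sign for p53 targets (median 0.09, mean -0.04, test up) and for lysosome and autophagy genes (median 0.10, mean 0.04, test down). For matrix proteases and inhibitors the mean was -0.50 and the test was up.

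Among the genes fixed in advance, many went in opposite directions or were called with 1 siRNA. The G1 cyclin CCND1 was at 0.48 with siGOLM1-1 and -0.90 with siGOLM1-2, the transcription factor MYC at -0.57 and 0.33, STAT3 at -0.40 and 0.51, and the chaperone HSPA5 at 0.47 and -0.48. Each of these differed between the siRNAs with edgeR adjusted p of 2.2e-05 or less. HSPA5 was not called with siGOLM1-1 against control replicates 3 and 4 alone (0.39) or with siGOLM1-2 against replicates 1 and 2 alone (-0.38), nor MYC with siGOLM1-2 against replicates 1 and 2 (0.30). The cell-cycle inhibitor CDKN1A rose by 0.93 with siGOLM1-1 and was at 0.09 with siGOLM1-2, and the stress factor DDIT3 was at 1.56 and 0.10. The receptor EGFR was at -0.13 and 0.77. FURIN, a Golgi protease, rose with both (0.44 and 0.44). The Golgi protein gene CASC4, a relative of GOLM1, was at 0.14 (adjusted p = 0.25) and 0.65. VIM of the mesenchymal cytoskeleton was at 0.64 and 0.12, CREB1 at 0.25 and -0.38 and AGO2 at -0.55 and -0.16. CREB1 with siGOLM1-1 was not called with control replicates 1 and 2 alone (0.17), without control replicate 4 (0.20) or siGOLM1-1 replicate 3 (0.20) or with library totals alone (0.20), and AGO2 not with control replicates 3 and 4 alone (-0.34).

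The secreted factors among them varied with the libraries. MMP2 was at 0.71 and 1.64, and with control replicates 1 and 2 alone at 0.26 with siGOLM1-1 and not called. With replicates 3 and 4 alone it was at 1.38 and 2.32. MMP2 with siGOLM1-1 was also not called without control replicate 4 (0.55), siGOLM1-1 replicate 1 (0.65) or siGOLM1-1 replicate 4 (0.68). MMP9 was at -0.10 and 4.88, or 3.80 without siGOLM1-2 replicate 4. IFIT1 fell with siGOLM1-1 (-2.24) and was at 0.46 with siGOLM1-2 (adjusted p = 0.20). Against control replicates 1 and 2 alone it was at -1.56 and 1.14, both called, and against replicates 3 and 4 alone at -2.69 and 0.02, the latter not called. Not called with either siRNA were CDH1 (0.09 and 0.09), FN1 (-0.35 and 0.28), ERBB2 (0.02 and 0.13), MKI67 (-0.10 and -0.64), MMP14 (-0.04 and -0.16), CD274 (-0.32 and 0.42), CAV1 (-0.40 and -0.25) and SOX2 (-0.31 and 0.56). Calls of 2 of these genes depended on the control pair. SOX2 was called lower with siGOLM1-1 against control replicates 1 and 2 alone (-0.91) and higher against replicates 3 and 4 alone (0.73). With siGOLM1-2 it was at -0.03 and not called against the former, and at 1.61 and called against the latter. ERBB2 was called higher with both siRNAs against replicates 1 and 2 alone (0.24 and 0.34), and not against replicates 3 and 4 alone (-0.15 and -0.04).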

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

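The search for words was planned. The tests of their match to the GOLM1 transcript and of 3' UTR properties, of the control siRNA, of the lower GOLM1 level and of the other splits of the libraries were chosen after the results were seen, as was the margin of 2 SE by which the quartiles of DNA replication and mitosis were judged.

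In 52 of 589 groups of 4 libraries, taken over the named genes and over total counts and mitochondrial share, 1 library stood apart from the other 3 by Dixon's ratio. Chance gives about 1 in 20. The ratio sets the gap of that library against the range of its group, so small differences can pass. GOLM1 in siGOLM1-1 replicate 4 was at 37.5 CPM against 38.7 to 38.9 in the others of its group. IL6 in siGOLM1-2 replicate 4 was at 17.4 CPM against 2.43 to 3.71. Of the 52, 25 were in siGOLM1-2 replicate 4. That library held (CPM) 482 of CAV1, 10.3 of MMP9, 1160 of VIM, 29.6 of C1orf116, 6.72 of SPNS2, 6.4 of TMEM173, 40.1 of C4BPB, 17.4 of IL6, 23.8 of CRISPLD2, 55.1 of OSBP2, 11.9 of SEMA7A and 22.7 of TMOD1. It also held 491 of SERPINE2, 58.7 of BTG2, 126 of DUSP5, 83.6 of TGIF1, 1010 of RPL15, 8.41 of COPG2, 175 of HLA-E, 210 of MMP7, 86.0 of INSIG1, 14.7 of HILPDA, 35.3 of NR4A1, 425 of CLDN2 and 70.8 of PLAU.

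In the siGOLM1-1 group, replicate 1 stood apart with 1.95 CPM of CD274, 521 of MKI67, 962 of VIM, 2.94 of C10orf10, 1.22 of DLGAP1, 346 of TIMP2 and 82.3 of KDM3A. Replicate 2 did so with 35.1 of MAN2A2 and 494 of RPS13, and replicate 3 with 107 of CDH1, 1.28 of PTGER4, 128 of NT5E, 72.9 of AMOTL1 and 34.9 of GADD45B. Replicate 4 did so with 37.5 of GOLM1, 2.01 of C1orf116, 368 of GALNT1 and 22.2 of RFC4. In the control, replicate 1 held 90.2 of VLDLR and 30.7 of TNRC6B, replicate 2 held 7.96 of CCNE2, replicate 3 held 39.2 of NDUFB5, and replicate 4 held 102 of ABCA3, 35.3 of NFKB1 and 93.6 of MTHFD2. siGOLM1-2 replicate 1 held 0.464 of C7 and replicate 2 held 10.6 of CD14.

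In the direct test of the siRNAs, 7 lists differed by camera at the preset correlation, and 0 with an estimated correlation. The median log2 difference was 0.12 for Golgi structure proteins, 0.45 for the amino acid response, -1.03 for the interferon response, -0.38 for antigen presentation, 0.41 for TGF-beta targets, 0.36 for hypoxia and glycolysis and 0.66 for NRF2 targets.

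For each siRNA, genes with a certain 7-base word in the 3' UTR were lower more often than genes without it. The shares below are of genes with or without the word. The share of lowered genes that hold it was not computed. With siGOLM1-1, 39.2% of the 1642 genes with ACTCTGA were lower against 23.8% of those without, and with siGOLM1-2, 42.7% of the 1070 genes with AAGTCTA were lower against 23.8%. After adjustment for 3' UTR length, base composition and expression level, the smaller of the 2 absolute z values was -12.9, beyond the 4.86 that permutations reached, which argues against those properties as the whole cause in genes with an annotated 3' UTR. The 8-base words CACTCTGA and AAGTCTAA each occurred 1 time in the GOLM1 transcript used for the 3' UTR and in 2 of 4 protein-coding GOLM1 transcripts, CACTCTGA outside the 3' UTR. Base composition of the transcript used gives both with a chance of 0.0022, so a match to the guide strand of each siRNA is a candidate explanation. The guide sequences are not in the labels, so this was not tested on them.

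DNA replication and mitosis genes were lower with both siRNAs. Without members that hold a word or lack an annotated 3' UTR, the highest upper quartile of members was -0.208 (SE 0.0615). This argues against the words ACTCTGA, AAGTCTA and TTACAAA in the members' own 3' UTRs as the whole cause. Members with other words of lowered genes were kept. Among such words were CACTCTG (z -12.4 with siGOLM1-1 after adjustment) and AGTCTAA (z -11.0 with siGOLM1-2 after adjustment). The fit therefore cannot decide on those words. The SEs of quartiles come from resampling members, which are not independent replicates. These SEs, and the margin of 2 SE, therefore do not measure the spread between libraries. With 1 surrogate variable or either pair of controls, both lists kept their calls at the preset correlation. With an estimated correlation, tested on all libraries, neither list was called (lowest adjusted p = 0.297). In the fits with the surrogate variable or a pair of controls, the highest upper quartile, that of mitosis with siGOLM1-1 against control replicates 3 and 4, was -0.00448 (SE 0.0626). A structure of the libraries within groups may thus account for a part of the mitosis change with siGOLM1-1, while the DNA replication quartiles lay at -0.28 or below. An effect of the control siRNA cannot be told apart from one of the knockdown without untransfected cells. The median difference of mitosis genes between the siRNAs was 0.46, not called in the main fit (camera adjusted p = 0.0545) and called in 14 of 23 alternatives. Such a difference can only show that a part is not from the control. The words of genes higher with both leave an effect of the control siRNA open. The word TTACAAA led them only after the adjustment (z 5.1 and 5.2 before, 7.8 and 7.3 after), while GCCCCGG (9.4 with siGOLM1-1) and CCTGGGG (10.0 with siGOLM1-2) ranked above it before.

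Interferon response genes were higher with siGOLM1-2. Without each of the 8 libraries of the comparison in turn, the lowest median was 0.83, which argues against 1 library. With GOLM1 lower still with siGOLM1-1, the list differed between the siRNAs by a median of -1.03. The lower GOLM1 level alone thus does not explain the values of both siRNAs. With siGOLM1-1, 9 members were higher and 16 lower (median -0.37), and the list was not called. The comparison cannot tell which siRNA departs from the effect of lower GOLM1. Effects of an siRNA on other targets, or a response to its sequence, may account for the difference. Without members that hold a word or lack an annotated 3' UTR, the median with siGOLM1-2 was 0.95, and neither explanation was tested further.

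Among the 35 splits of the 8 libraries of each comparison, fitted on those libraries alone, 1 split, the real one, gave as many genes as observed. It called 7657 genes with siGOLM1-1, 8279 with siGOLM1-2 and 9348 between the siRNAs, and the highest other split called 0, 0 and 143. The most genes were thus called where the libraries were divided by their group. Every other split mixes the groups, so a strong difference between them enters the spread and lowers the counts. The low counts of the other splits therefore do not exclude chance, and 1 of 35 is the smallest share the test can reach. Nor can the test tell an effect of the siRNAs from another difference between the libraries of the groups.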

How the results depend on the processing

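The pairs of controls, the surrogate variable and the fits without words were added after the data were seen. Over all alternatives, named genes gave 14140 values on the same side of the threshold, 161 newly called, 254 no longer called and 5 reversed. The lists gave 2105, 63, 61 and 0 in that order. Direction was compared only where the main fit or the alternative gave a call. Changes of sign between uncalled values are therefore among the 14140. For lists, the direction was that of the camera test, so a median that changed sign was not counted as reversed. The reversals were PRR15L with siGOLM1-2 (0.58), and SCNN1A (0.17), PER1 (0.86) and MAP2 (1.28) with siGOLM1-1, all against control replicates 1 and 2 only, and SOX2 with siGOLM1-1 (0.73) against control replicates 3 and 4 only; PER1, MAP2 and SOX2 were not called with all controls. The test against an absolute log2 fold change of 0.5, stricter by construction, called 2590, 2189 and 3759 genes for siGOLM1-1, siGOLM1-2 and the direct comparison. The estimated correlation called 0, 0 and 0 lists; fry called 20 with siGOLM1-1 and 18 between the siRNAs, and no filter on low counts called 17 lists between the siRNAs; the cause was not tested. With split controls, 1913, 1892, 1896 and 1893 genes were shared in the same direction where siGOLM1-1 had replicates 1 and 3, 1 and 4, 2 and 3, or 2 and 4; fewer controls entered each fit. Leaving out 1 library gave 7472 to 8700, 6904 to 8329 and 8630 to 9614 genes called, 2645 to 3421 shared, GOLM1 at -3.28 to -3.22 and -3.01 to -2.91, and 13 to 14, 15 to 16 and 6 to 10 lists. Replicate numbers did not pair the libraries (correlations of deviations from -0.36 to 0.50, 6 of 12 over 0.1, and 3 of 12 libraries correlated best with their own number); with the replicate block, 8389, 7929 and 9613 genes and 13, 16 and 10 lists were called. In a simulation with 200 changed genes, where the p cutoff is stricter than in the data, changes of 0.5 on the log2 scale were called in 36.4% and 39.4% of genes; the share missed in the data was not estimated.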

Other observations

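The test of the glucocorticoid list was planned before its members were looked at, after the falls of FKBP5, PER1 and SCNN1A had been seen.

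Lists that were not called as a whole held single genes with differences between the siRNAs, each with edgeR adjusted p of 3.31e-06 or less in the direct comparison. The receptor MET was at -1.46 with siGOLM1-1 and 0.90 with siGOLM1-2, and TGFA, a ligand of EGFR, at -1.26 and 1.66. Of the respiratory chain, SDHD was at -1.06 and -0.12 and NDUFB5 at -0.19 and -1.64. The surfactant transporter ABCA3, a lung lineage gene, was at -0.76 and 0.55. In the unfolded protein response list, HYOU1 was at -1.29 and 0.14 and EDEM1 at -0.38 and 0.74.

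FKBP5 and SCNN1A, known as induced by glucocorticoids, fell with both siRNAs and PER1 with siGOLM1-2, mostly against control replicates 3 and 4. Control replicates 1 and 2 held 22.8 and 22.6 CPM of FKBP5, and replicates 3 and 4 held 221 and 225. The siGOLM1-1 libraries held 14.9 to 19.1. For SCNN1A these values were 12.2 and 13.8, 203 and 215, and 10.8 to 17. Most of these falls thus lay between the control pairs, and the cause of that difference was not tested. Lower glucocorticoid receptor output with the siRNAs was examined as a possible cause of the falls. A list of 14 further genes known as induced by glucocorticoids was tested, with 11 members among the genes tested. With siGOLM1-1, 6 were higher and 2 lower, with median 0.71, and with siGOLM1-2, 2 were higher and 5 lower, with median -0.28. The camera test of limma, adjusted over both siRNAs, gave adjusted p = 0.131 for a rise and adjusted p = 0.316 for a fall. The prediction that the list falls with both siRNAs was not met. Against control replicates 1 and 2 alone the medians were 0.72 and 0.16, and against replicates 3 and 4 alone 0.26 and -0.66.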
